A study of Caenorhabditis elegans with 9 samples.

How the data were processed

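Total RNA from 20 hand-picked L4 larvae per sample was amplified by 1 round of T7 transcription, labelled with biotin and hybridised to 1 Affymetrix C. elegans array, per the labels. There were 9 arrays, 3 each from the wild type, ogt-1(ok430) and oga-1(ok1207). The deposited table holds log2 probe set signals for 22625 probe sets, which the authors had put on a common scale, since the array means agree at 5.91. The submitters' processing notes list MAS5, RMA and Partek, with no role or version, and which of them made the table is not given in the sources used here. The values lie between 3.49 and 14.9, with no zeros, negative or missing values, so no pseudocount was added. The scan files were not used here.

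Control probe sets, 77 in number, were left out of the tests, which leaves 22548 with no filter on signal. Symbols came from the platform's annotation and were updated through the gene identifiers to current names. A single gene was named by 20766 probe sets, several by 887 and none by 895, and 17118 genes were measured. For a gene with several probe sets, the one with the highest mean signal over the 9 arrays stood for it in lists and named values. No coordinates are given, because the genome build behind the array was not analysed here.

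The log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with strain as the only term and all 9 arrays, which leaves 6 residual degrees of freedom. The 3 comparisons were ogt-1 against wild type, oga-1 against wild type, and ogt-1 against oga-1. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided, and "rose", "fell", "higher" and "lower" gene counts refer to such calls. Group values are means with the SD of 3 arrays, and all differences are in log2 unless given as folds. Control probe sets were compared by exact permutation tests, two-sided, which cannot give a p below 0.1 with 3 against 3 arrays.

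The tests, the alternatives, the 36 gene lists and the rule for naming genes were fixed before the data were examined. The rule names ogt-1 and oga-1, then the 10 largest rises and 10 largest falls among called genes whose 3 mutant arrays all lie on one side of the 3 wild-type arrays. It then names up to 2 members per direction of each list that was called or had at least 2 called members, by smallest p, the 5 shared or opposite changes of the mutants largest by mean size, and the 5 largest differences per direction between the mutants. Members of the lists were written from general knowledge or by symbol family. Other list members given here, such as pmk-1, were chosen after their values were seen. Of the PMK-1-dependent genes 7 of 22 also stand in another list, as do 17 of 26 DAF-16-activated genes, 6 of 22 intestine genes, 5 of 71 in the lysozyme list and 4 of 220 C-type lectins.

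Each list was tested with limma's camera, which compares the list with all other genes, at a preset correlation of 0.01 between genes, and adjusted over the 36 lists within a comparison. Alternatives were camera with the correlation estimated per list, and fry. The correlation and covariance of the changes of the 2 mutants were set beside 100 simulations with no effect and shared wild-type arrays. On simulated data of the same size with independent noise, 50 probe sets were changed by 0.5 log2, 100 by 1 and 50 by 2. The fit recovered 54%, 56% and 40% of the changes of 0.5 in the 3 comparisons and at least 97% of those of 1. Between 2.78% and 5.91% of its calls were unchanged probe sets. The real comparisons called 3891, 58 and 5381 probe sets, so these shares need not hold for them.

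Other alternatives were the 2 groups alone, quantile normalization, median centring, only probe sets above the median or in the top quartile of mean level, an intensity trend with robust variance, array weights, an adjusted p under 0.1, a 1.5-fold minimum, other or averaged probe sets of a gene, leaving out each array, and the replicate number as a block. The labels number the replicates 1 to 3 in every strain without saying that equal numbers belong together. Of the 9 pairs of same-numbered arrays from different strains, the deviations from the strain mean correlated at -0.173 to 0.244, and 3 of 9 arrays correlated best with one of their own number, so the arrays were taken as unpaired. With the replicate block 4039, 77 and 5578 probe sets were called, in place of 3891, 58 and 5381. Chosen after the data were seen were the spread of each array as a covariate, and leaving out together the 3 arrays whose SD over probe sets exceeded 1.8, which leaves 1 oga-1 array, assumed to vary like the other groups.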

Results

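Transcript levels were measured in C. elegans larvae of the fourth larval stage (L4), the last before adulthood, in the wild type and in mutants of the 2 enzymes that cycle O-GlcNAc on proteins. O-GlcNAc is a sugar attached to serines and threonines of nuclear and cytoplasmic proteins. The gene ogt-1 encodes the O-GlcNAc transferase, which adds it, and oga-1 encodes the O-GlcNAcase, which takes it off. Each of the 3 groups, wild type, ogt-1(ok430) and oga-1(ok1207), held 3 arrays, which the labels call biological replicates. Each array was made from 20 fed larvae picked by hand and matched for age by how far the vulva had developed. The 9 arrays had the same mean log2 signal, 5.91, and medians from 5.21 to 5.30. Across probe sets, which are not independent replicates, arrays of the same strain correlated at r = 0.990 to 0.994 in the wild type, 0.991 to 0.993 in ogt-1 mutants and 0.990 to 0.992 in oga-1 mutants. Wild-type and oga-1 arrays correlated at 0.986 to 0.992, and wild-type and ogt-1 arrays at 0.963 to 0.976. The number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.11, and whether replicates came from separate cultures is not given in the labels.

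The ogt-1 transcript itself fell in ogt-1 mutants, and the oga-1 transcript did not pass the test in oga-1 mutants. The stronger ogt-1 probe set (chromosome III) read 7.90 ± 0.07 (SD, n = 3) in the wild type, 7.03 ± 0.08 (SD, n = 3) in ogt-1 mutants and 7.94 ± 0.13 (SD, n = 3) in oga-1 mutants. Its log2 change in ogt-1 mutants was -0.87 with a standard error of 0.09 (limma adjusted p = 8.9e-05), and the gene's other probe set fell by 0.42. The 3 oga-1 probe sets, on chromosome X, were dim in every group, between 4.57 and 5.32 on average. They differed by -0.32, -0.28 and -0.25 in oga-1 mutants (limma adjusted p = 0.22, 0.31 and 0.23), and none was called. Whether these probe sets lie in the deleted parts of the genes was not analysed here, so the values do not measure how much functional transcript remained.

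Transcript levels differed across the genome between ogt-1 mutants and the wild type, and the largest differences were increases. The largest rise was that of cpr-4, a cathepsin B-like cysteine protease made in the intestine, from 7.10 ± 0.07 to 12.65 ± 0.33 (SD, n = 3), a 46.8-fold increase (limma adjusted p = 1.5e-09). The gene T27E7.1 rose 36.7-fold, from 5.84 ± 0.37 to 11.04 ± 0.10 (SD, n = 3), and the long noncoding RNA tts-1 rose 15.9-fold, from 5.65 ± 0.30 to 9.64 ± 0.20 (SD, n = 3). The immune-response gene dod-24 rose 11-fold, from 8.37 ± 0.06 to 11.87 ± 0.44 (SD, n = 3). The largest falls among named genes were 8.88-fold for pud-3, from 10.85 ± 0.55 to 7.70 ± 0.74 (SD, n = 3), and 6.30-fold for Y38E10A.14.

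The other genes among the 10 largest rises were T26E4.10 (27.1-fold), C23G10.11 (25.6-fold), T26E4.9 (20.0-fold), B0348.2 (18-fold), nspb-6 (15.2-fold) and B0310.6 (11.8-fold). Several of these varied widely between the ogt-1 arrays: C23G10.11 read 9.33 ± 1.70 (SD, n = 3) and T26E4.10 read 9.15 ± 1.08 (SD, n = 3). The other genes among the 10 largest falls included the ABC transporter pmp-5 (log2 change -2.25), the astacin protease dpy-31, which is needed for cuticle collagen processing (-2.14, but -0.91 and -0.73 by its other probe sets), and the antimicrobial peptide cnc-7 (-2.06). They also included H11L12.1 (-2.03), the stearoyl-CoA desaturase fat-7 (-1.95), pud-4 (-1.92), the kynureninase kynu-1 of tryptophan breakdown (-1.84) and F38B6.4 (-1.82, and -1.16 by its other probe set). The adjusted p-values of the 20 genes ran from 1.5e-09 to 0.0053, and all 20 kept the call when any 1 of the 9 arrays was left out.

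Of 22548 probe sets tested, 3891 were called in ogt-1 mutants, 1827 higher and 2064 lower, which is 17.3% of those tested. They named 1562 genes with a higher and 1805 with a lower probe set, and 7 of these genes had probe sets in both directions. Changes of at least 2-fold were mostly increases, in 536 probe sets against 111 decreases, and changes of at least 4-fold were 76 increases and 8 decreases. The lowest value of an array was 3.49 to 3.61, and mean signals in the 5 dimmest of 10 groups by level reached 5.27. Dim probe sets thus had less room for large falls than for large rises. The ogt-1 and wild-type arrays did not overlap in 33.1% of all probe sets, where chance gives 10%. Requiring a 1.5-fold change lowered the count to 2052.

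**Figure D1:**
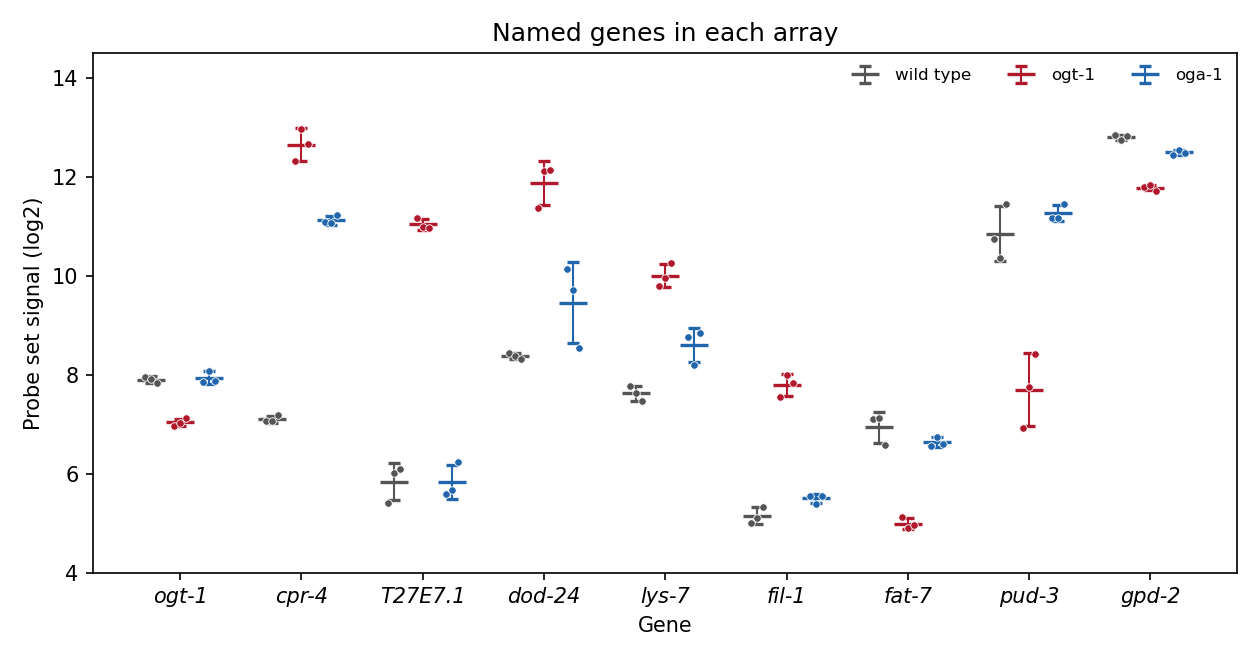
Log2 signal of 9 genes in each array of the wild type, ogt-1 and oga-1 mutants; points are single arrays, and bars give the mean and SD of 3 arrays. The ogt-1 transcript was lower in ogt-1 mutants by a log2 change of -0.87, while cpr-4 was higher in both mutants, by 5.55 in ogt-1 and 4.02 in oga-1 mutants.

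Lists of innate defence genes and of histones were called higher in ogt-1 mutants, by limma's camera with its preset correlation between genes. The list of PMK-1-dependent immune genes, named for the p38 kinase PMK-1, also held members of the PMK-1 pathway itself. Of its 22 measured genes, 15 rose and none fell, with a median log2 change of 1.41 (adjusted p = 2.0e-10, and adjusted p = 0.11 with an estimated correlation). The risers included the C-type lectins clec-4 (2.15) and clec-85 (2.22), and dod-24 (3.50). The kinases and transcription factor of the pathway in this list were not called: pmk-1 differed by -0.18, sek-1 by -0.20 and atf-7 by -0.29. Of 71 lysozymes, saposins and antimicrobial peptides, 23 rose, among them lys-7 (2.38) and spp-18 (1.39), and 3 fell, with a median of 0.29 (adjusted p = 1.1e-07, and adjusted p = 0.21 with an estimated correlation). Of 220 C-type lectins, 36 rose, clec-66 by 2.85, and 2 fell, with a median of 0.06 (adjusted p = 1.4e-05, and adjusted p = 0.21 with an estimated correlation). Histone genes rose in 20 of 35 and fell in 1, his-72, a histone H3.3 gene, with a median of 0.61 (adjusted p = 5.0e-12, and adjusted p = 0.087 with an estimated correlation). The histone his-4 changed by 1.65 and the linker histone hil-2 by 1.57. The call of his-72 was lost when wild-type array 1 or 2 or ogt-1 array 2 was left out.

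Adjusted over the list alone, 15 PMK-1-dependent genes were higher and 0 lower, as were 29 and 5 of the lysozyme list, 36 and 2 of the C-type lectins, and 25 and 3 of the histones. The added bacterial hybridisation controls, 18 probe sets that measure how well labelled RNA was read, were also higher in ogt-1 mutants, at 9.38 ± 0.12 (SD, n = 3) against 9.11 ± 0.09 (SD, n = 3) in the wild type. That difference of 0.277 had an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 arrays allow.

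Lists of neuropeptides, insulin-like peptides, glutathione S-transferases, intestine genes and DAF-16-repressed genes were called higher as well. Of 74 neuropeptide genes 23 rose and 0 fell, with nlp-17 at 1.29 and flp-15 at 1.74 (1.19 and, not called, 0.13 by its other probe sets) and a list median of 0.13 (adjusted p = 2.0e-07, and adjusted p = 0.21 with an estimated correlation). Of 24 insulin-like peptide genes 10 rose and 0 fell, among them ins-22 (1.67) and ins-6 (0.86), with a median of 0.17 (adjusted p = 9.2e-05, and adjusted p = 0.17 with an estimated correlation). Of 45 glutathione S-transferases 13 rose and 2 fell, with gst-13 at 1.49, gst-20 at 1.23, gst-39 at -0.63 and a median of 0.15 (adjusted p = 1.8e-05, and adjusted p = 0.057 with an estimated correlation). In the intestine list, 8 of 22 rose and 2 fell, with a median of 0.18 (adjusted p = 6.1e-04, and adjusted p = 0.21 with an estimated correlation). There cpr-4 and the ferritin ftn-1 (1.86) rose, and the intestinal actin act-5 (-0.91) and the acid phosphatase pho-1 (-1.19) fell. Among genes repressed by the FOXO factor DAF-16, 8 of 22 rose and 2 fell, with dod-24 and dod-23 (1.5) rising, cyp-34A8 (-0.95) falling and a median of 0.11 (adjusted p = 7.0e-04, and adjusted p = 0.087 with an estimated correlation). Another list also holds 15 of these 22 genes. Higher and lower genes, adjusted over the list alone, numbered 24 and 1 for neuropeptides, 10 and 1 for insulin-like peptides, 13 and 2 for glutathione S-transferases, 8 and 3 for the intestine and 9 and 2 for DAF-16-repressed genes. The hybridisation controls, higher by 0.277, moved with these lists too. Random lists matched on mean level had medians mostly from -0.22 to 0.21 for the intestine list. Its median of 0.18 fell within these limits, at percentile 96.46, so level alone could give a median of this size. The medians of neuropeptides, insulin-like peptides, glutathione S-transferases and DAF-16-repressed genes lay outside theirs, at percentiles 100, 99.99, 100 and 99.02.

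The list of sperm genes was called higher and that of oocyte genes lower in ogt-1 mutants. Of 77 sperm genes, which include the major sperm proteins, 26 rose and 1 fell, with nspd-9 at 1.78, ssp-33 at 1.49 and a median of 0.27 (adjusted p = 8.9e-10, and adjusted p = 0.38 with an estimated correlation). Of 30 oocyte and maternal genes 14 fell and 0 rose, with the Y-box protein cey-3 at -0.71, the oocyte maturation factor oma-2 at -0.67 and a median of -0.34 (adjusted p = 6.3e-06, and adjusted p = 0.40 with an estimated correlation). Of the 5 vitellogenins, the yolk proteins made in the intestine, 3 fell, vit-1 by a log2 change of -0.87, with a median of -0.35 (adjusted p = 0.016, and adjusted p = 0.39 with an estimated correlation). That call was lost among probe sets above the median level. The list of germline and meiosis genes was not called: 4 of 40 rose, among them spo-11 (0.94), and 7 fell, among them the germ-granule helicase glh-1 (-0.87, and -0.50 and not called by its other probe set). Adjusted over the list alone, 40 sperm genes were higher and 2 lower, 1 oocyte gene higher and 19 lower, and 3 vitellogenins lower. The sperm gene that fell, spe-51 (-0.36), lost its call when any 1 of wild-type arrays 2 and 3 and the ogt-1 arrays was left out. The hybridisation controls, higher by 0.277, moved with the sperm genes as well.

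The lists of the proteasome, ribosomal proteins, the respiratory chain and sugar metabolism were called lower in ogt-1 mutants. Of 34 proteasome genes 18 fell, among them pbs-1 (-1.01) and pbs-6 (-0.79) of the catalytic core, and 1 rose, rpn-7 (0.68), with a median of -0.41 (adjusted p = 2.7e-08, and adjusted p = 0.30 with an estimated correlation). Of 62 ribosomal protein genes 25 fell and 0 rose, with rps-9 at -0.61 (-0.29 and not called by its other probe set), rpl-7 at -0.59 and a median of -0.23 (adjusted p = 1.2e-07, and adjusted p = 0.21 with an estimated correlation). In the mitochondrial respiratory chain 21 of 51 fell, such as asg-2 (-0.91) and cox-6C (-0.93), and 3 rose, with a median of -0.28 (adjusted p = 1.7e-07, and adjusted p = 0.21 with an estimated correlation). In glycolysis, gluconeogenesis, trehalose and glycogen metabolism 13 of 31 fell, led by the glyceraldehyde-3-phosphate dehydrogenases gpd-3 (-1.09) and gpd-2 (-1.02), and 1 rose, with a median of -0.35 (adjusted p = 2.3e-05, and adjusted p = 0.29 with an estimated correlation). The riser was the trehalase tre-1 (0.42), whose call was lost when wild-type array 1 or 2 or ogt-1 array 3 was left out. With p adjusted over the list alone, 2 and 24 genes were higher and lower in the proteasome list, 1 and 32 in the ribosomal, 3 and 26 in the respiratory and 2 and 18 in the sugar list. The control probe sets of actin, whose 3' minus 5' signal reads how far amplified RNA reached, differed too, at 4.04 ± 0.12 (SD, n = 3) in ogt-1 mutants against 4.77 ± 0.05 (SD, n = 3) in the wild type (exact permutation p = 0.1, two-sided). The 3' minus 5' signal of Gapdh differed by -0.379 and the hybridisation controls by 0.277 (exact permutation p = 0.1 for each, two-sided).

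Fat metabolism genes went both ways, with more falling. Of 89 measured, 23 fell, including fat-7 (-1.95) and let-767 (-1.14), and 9 rose, including the lipase fil-1 (2.65), with a median of -0.13 (adjusted p = 0.016, and adjusted p = 0.38 with an estimated correlation). Of 9 genes of the hexosamine pathway and O-GlcNAc cycling 3 fell, among them ogt-1 itself and gfat-1 (-0.78), whose enzyme starts hexosamine synthesis, and 0 rose, with a median of -0.25 (adjusted p = 0.016, and adjusted p = 0.39 with an estimated correlation). Since ogt-1 is the mutated gene, its fall is no independent support, and the hexosamine list was not tested without it, here or between the mutants. In the core of insulin and FOXO signalling 3 of 17 fell and 0 rose, with the 14-3-3 proteins par-5 at -0.66 and ftt-2 at -0.57 and a median of -0.14 (adjusted p = 0.022, and adjusted p = 0.52 with an estimated correlation). Of 64 UDP-glucuronosyltransferases 11 fell and 3 rose, with ugt-26 at -0.94 and a median of -0.09 (adjusted p = 0.038, and adjusted p = 0.40 with an estimated correlation). Of 146 cuticle collagens 4 rose and 4 fell, with col-127 at 0.52, col-76 at -0.51 and a median of 0.05 (adjusted p = 0.049, and adjusted p = 0.71 with an estimated correlation). The higher and lower genes adjusted over the list alone were, in the order given, 9 and 27, 0 and 5, 0 and 3, 3 and 13, and 2 and 3. Each of these 5 list calls also ended without 1 array: ogt-1 array 1 or wild-type array 3 for fat metabolism, ogt-1 array 1 for the hexosamine list, wild-type array 1 or ogt-1 array 2 for insulin and FOXO signalling, ogt-1 array 3 for UDP-glucuronosyltransferases, and wild-type array 1 or ogt-1 array 2 or 3 for collagens. The last pair of calls was also lost after quantile normalization. All but the call of fat metabolism were lost among probe sets above the median level, and those of insulin and FOXO signalling and of collagens with fry. Random lists matched on mean level had medians mostly from -0.27 to 0.15 for insulin and FOXO signalling. For the hexosamine list they lay mostly from -0.35 to 0.25. Both observed medians fell within these limits, at percentiles 21.96 and 7.27, so level alone could give medians of this size. Those of fat metabolism, UDP-glucuronosyltransferases and collagens lay outside theirs, at percentiles 1.04, 0.34 and 99.62. The control probe sets differed along with these lists, the hybridisation controls by 0.277 and the 3' minus 5' signal by -0.729 for actin and -0.379 for Gapdh (exact permutation p = 0.1 for each, two-sided).

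The remaining lists were not called in ogt-1 mutants, although single members changed. Genes of the molting cycle were called in 3 of 73, with the hedgehog-related wrt-5 at 1.04, and genes of vulval development in 4 of 27, all lower, with the glycosyltransferase sqv-5 at -0.83. In muscle 6 of 29 rose, with the troponin C tnc-2 at 2.49, and 4 fell, with the troponin I unc-27 at -0.87. Of 32 genes of oxidative stress defence 5 rose, such as the glutathione peroxidase gpx-3 (2.03), and 6 fell, such as the peroxiredoxin prdx-2 (-0.62). Of 26 DAF-16-activated genes 6 rose, with dod-6 at 2.21, and 3 fell. Higher and lower genes numbered 4 and 12 of 59 for autophagy and the lysosome, 5 and 9 of 73 for cytochrome P450s, 9 and 4 of 259 for nuclear hormone receptors, and 3 and 1 of 35 for neuronal function. They numbered 0 and 5 of 24 for the dauer pathway, 1 and 4 of 23 for heat shock proteins, 2 and 3 of 19 for the endoplasmic reticulum stress response, 2 and 6 of 1280 for chemoreceptors, and 0 and 0 of 12 for male tail and male neuron genes. The test's direction differed from the sign of the median for molting and neuronal genes, and the muscle list had a median of -0.13 with a mean of 0.04.

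**Figure D2:**
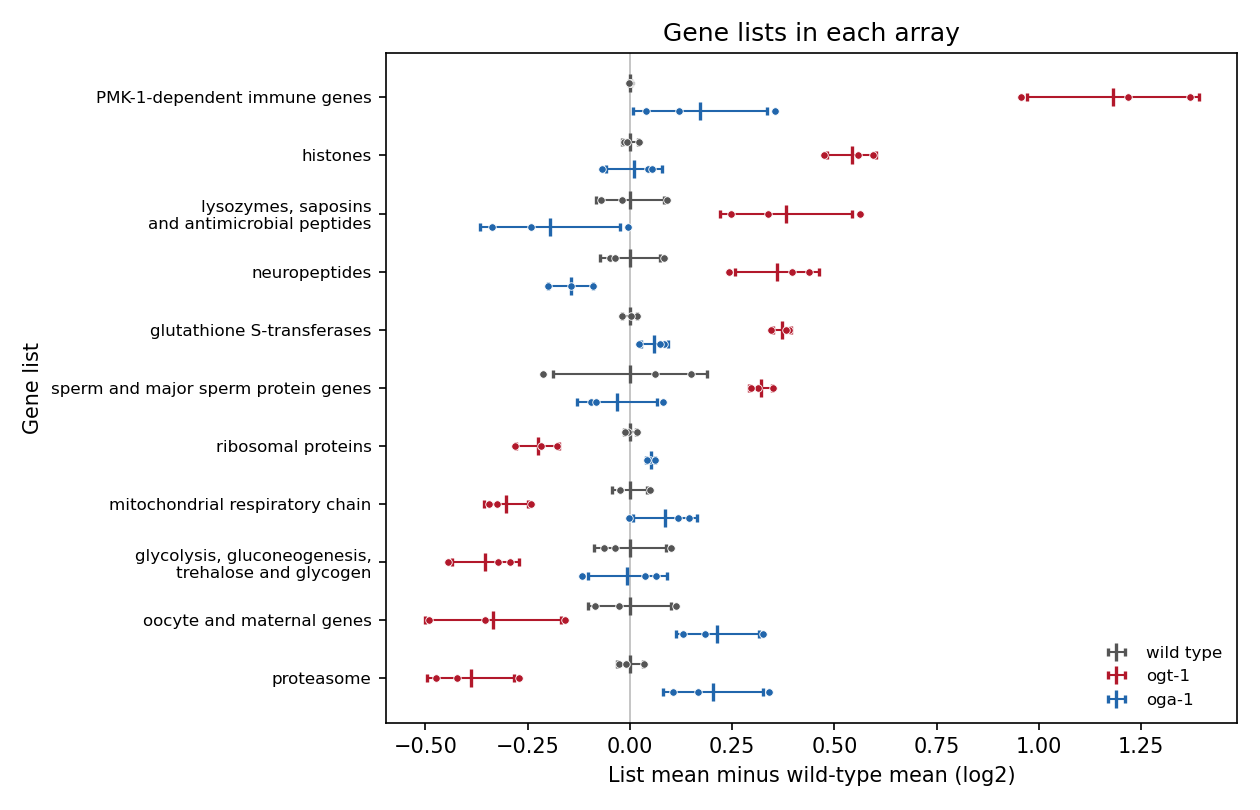
Mean log2 signal of the genes of 11 lists in each array, relative to the mean of the wild-type arrays; points are arrays, and bars give the mean and SD of 3 arrays per strain. The PMK-1-dependent genes stand highest in ogt-1 mutants, and the proteasome and oocyte lists lie below the wild type in ogt-1 and above it in oga-1 mutants.

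Few genes passed the test in oga-1 mutants, and again cpr-4 rose most, from 7.10 ± 0.07 to 11.12 ± 0.09 (SD, n = 3), 16.2-fold (limma adjusted p = 5.1e-08). Other increases were those of C27D8.3, 2.51-fold from 5.91 ± 0.13 to 7.23 ± 0.24 (SD, n = 3), F55G11.2, 2.5-fold from 7.06 ± 0.15 to 8.38 ± 0.28 (SD, n = 3), and the cadmium-responsive cdr-1, 2.32-fold from 6.02 ± 0.10 to 7.23 ± 0.20 (SD, n = 3). The gene mbug-1 rose 2.09-fold and the cytochrome P450 gene cyp-35D1 1.94-fold. The gene C55C3.3 fell 2.26-fold, from 6.37 ± 0.20 to 5.20 ± 0.25 (SD, n = 3). These 7 genes kept the call when any 1 array was left out.

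Other genes named by the rule were less stable in oga-1 mutants. The increases were idpp-7 (log2 change 1.38), cls-3 (1.21), the acid ceramidase asah-1 (1.13), the claudin-like clc-11 (1.03) and sax-2 (1.02). The decreases were F23F12.12 (-1.67), F15E6.4 (-1.5), the antimicrobial peptide nlp-33 (-0.94), scrm-4 (-0.89), sshk-1 (-0.76), rom-2 (-0.66), tin-10 (-0.66), F57A10.2 (-0.65) and svop-1 (-0.63). Their adjusted p-values lay between 0.0087 and 0.049. Of the 20 genes with the largest changes, 6 kept the call whichever array was left out. It was lost by 14 without wild-type array 1, by 13 without wild-type array 2, by 9 without oga-1 array 1, by 5 each without oga-1 array 2 or 3, by 4 each without wild-type array 3 or ogt-1 array 2, and by 2 without ogt-1 array 3.

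In oga-1 mutants 58 of 22548 probe sets were called, 43 higher and 15 lower, in 42 and 12 genes; 3312 had an unadjusted p under 0.05. After quantile normalization 91 were called and 54.9% of them were higher, in place of 74.1%, so the balance of directions rests on the scaling. The count was 9 without wild-type array 1, 13 without wild-type array 2, 21 without oga-1 array 1 and 89 without ogt-1 array 1, and 3 when the 3 arrays of widest spread, ogt-1 array 3 and oga-1 arrays 1 and 3, were left out together. With array weights it was 848. The arrays of the 2 strains did not overlap in 20.5% of probe sets, where chance gives 10%.

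Several gene lists were called in oga-1 mutants by limma's camera while few of their genes were. None of these list calls held with an estimated correlation, where the adjusted p was 0.54 for insulin-like peptides and 0.61 for the others. Proteasome genes had a median log2 difference of 0.21, with 0 of 34 called, oocyte and maternal genes 0.22 with 0 of 30, germline and meiosis genes 0.18 with 0 of 40, and autophagy and lysosome genes 0.12 with 0 of 59. The median was -0.12 for chemoreceptors, with 0 of 1280 called, -0.21 for insulin-like peptides, with 0 of 24, and -0.13 for neuropeptides, with 0 of 74. In the lysozyme list it was -0.17, with lys-7 (0.98) and spp-18 (0.60) higher and nlp-33 lower, and in the intestine list 0.14, with cpr-4 the called gene of 22. The members with the smallest p still missed the threshold, with 0.37 for the proteasome ATPase rpt-4, 0.56 for oma-2, 0.52 for the meiosis gene him-8 and -0.87 for ins-33 (limma adjusted p = 0.12, 0.065, 0.065 and 0.065). The other probe set of oma-2 read -0.022. In the cytochrome P450 list, not called itself, cyp-35D1 (0.96) and cyp-35A5 (0.79) rose. The calls of lys-7 and spp-18 were lost without any 1 wild-type array, ogt-1 array 2, or oga-1 array 1 or 3, that of spp-18 also without oga-1 array 2, and those of nlp-33 and cyp-35A5 without wild-type array 1 or 2. The actin 3' minus 5' signal was also lower in oga-1 mutants, at 4.20 ± 0.26 (SD, n = 3) against 4.77 ± 0.05 (SD, n = 3) in the wild type (exact permutation p = 0.1, two-sided).

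The camera adjusted p of these lists was 1.0e-07 for the proteasome, 7.7e-07 for oocyte genes, 2.2e-05 for germline genes, 1.2e-05 for autophagy, 2.8e-12 for chemoreceptors, 2.2e-05 for insulin-like peptides, 2.9e-04 for neuropeptides, and 0.0013 for both the lysozyme and intestine lists. By fry, a rotation test of whether a list's genes move one way, 0 of 36 lists were called. When p was adjusted over the list alone, 8 proteasome genes, 1 oocyte gene, 4 germline genes, 2 autophagy genes and 3 intestine genes were higher, 4 insulin-like peptides lower, 1 neuropeptide higher and 2 lower, 3 of the lysozyme list higher and 10 lower, and 0 chemoreceptors either way. Another 3 lists were called with smaller medians: the respiratory chain (0.07), the endoplasmic reticulum stress response (0.13) and ribosomal proteins (0.06), with camera adjusted p of 0.0039, 0.026 and 0.028 and an adjusted p = 0.61 with an estimated correlation. These 3 calls were lost after quantile normalization, where the respiratory chain's median was -0.02, and without oga-1 array 1 (respiratory chain), wild-type array 2 or oga-1 array 1 (stress response), and wild-type array 3 or oga-1 array 3 (ribosomal proteins). Adjusted over the list alone they held 1, 0 and 1 higher genes and 0 lower. With the spread of each array as a covariate 5 of the 12 lists kept the call, and the chemoreceptor median was -0.0077; with the 3 arrays of widest spread left out 4 of the 12 kept it, and the proteasome list did not. Of the lists not called, the median ran against the test's direction for oxidative stress defence, fat metabolism, UDP-glucuronosyltransferases, histones, and insulin and FOXO signalling, and the mean did for DAF-16-activated genes and glycolysis.

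The mutants were also compared with each other, which tests whether the effects of losing the transferase and losing the O-GlcNAcase differ. The genes T27E7.1 (log2 difference 5.21), T26E4.10 (4.89), C23G10.11 (4.72), B0348.2 (4.51) and T26E4.9 (4.36) were higher in ogt-1 than in oga-1 mutants. Lower were pud-3 (-3.56), pud-4 (-2.59), Y38E10A.14 (-2.11), sax-2 (-2.09), which acts in neuron morphology, and the ABC transporter haf-6 (-1.78). All 10 kept the call in every alternative run for single genes. Proteasome genes were lower in ogt-1 than in oga-1 mutants in 27 of 34 and higher in 1, with a median of -0.68, and oocyte genes were lower in 23 of 30, with a median of -0.62. With an estimated correlation the adjusted p was 0.17 and 0.27. Lysozymes and related peptides were higher in 35 of 71 and lower in 1, with a median of 0.50, and neuropeptides were higher in 30 of 74, with a median of 0.21, where the adjusted p was 0.12 and 0.12 with an estimated correlation.

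In the direct comparison 5381 probe sets were called, 2171 higher in ogt-1 mutants and 3210 lower, and 22 lists. The camera adjusted p was 1.9e-13 for the proteasome, 2.6e-10 for the oocyte list, 2.6e-10 for lysozymes and 5.0e-10 for neuropeptides, and no list was called with an estimated correlation, where the smallest adjusted p was 0.11. Adjusted over the list alone, higher and lower genes numbered 1 and 29, 0 and 23, 37 and 3, and 34 and 1. Other lists with higher medians in ogt-1 than in oga-1 mutants were the PMK-1-dependent genes (0.87), histones (0.65), insulin-like peptides (0.31), sperm genes (0.27), DAF-16-repressed genes (0.26), C-type lectins (0.11), chemoreceptors (0.09), cuticle collagens (0.07) and glutathione S-transferases (0.05). Other lists with lower medians were hexosamine genes (-0.50), vitellogenins (-0.49), the respiratory chain (-0.43), ribosomal proteins (-0.30), glycolysis (-0.29), germline and meiosis (-0.24), fat metabolism (-0.16), autophagy (-0.15) and UDP-glucuronosyltransferases (-0.07). The collagen call was lost without wild-type array 3, ogt-1 array 2 or 3, or oga-1 array 1 or 3, and that of UDP-glucuronosyltransferases without ogt-1 array 3 or oga-1 array 3. With fry the calls of chemoreceptors, germline and meiosis, and collagens were lost, among probe sets above the median level those of germline and meiosis and of UDP-glucuronosyltransferases, and with the spread covariate that of chemoreceptors. Leaving out the 3 arrays of widest spread lowered the probe set count to 2544 and ended the list calls of collagens, UDP-glucuronosyltransferases and fat metabolism.

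Genes called in both mutants included 19 that were higher and 4 that were lower in each. Beside cpr-4, the shared increases largest by the mean of the 2 changes were those of F55G11.2 (2.53 in ogt-1 and 1.32 in oga-1 mutants), F01D5.5 (2.48 and 0.96), the C-type lectin clec-76 (2.57 and 0.87) and clc-11 (2.35 and 1.03). The shared decreases were those of C55C3.3 (-1.16 and -1.17), scrm-4 (-1.0 and -0.89), tin-10 (-0.99 and -0.66) and svop-1 (-0.48 and -0.63). The other probe set of svop-1 differed by -0.23 and 0.05 and was called in neither mutant. In opposite directions went 10 genes, among them sax-2 (-1.07 and 1.02), haf-6 (-1.25 and 0.53), the chromodomain protein cec-4 (-0.68 and 0.78), W10G11.3 (1.48 and -0.58) and F23F12.12 (0.72 and -1.67). Of these 14 genes, cpr-4, F55G11.2 and C55C3.3 kept both calls whichever array was left out, and the other 11 lost the call in oga-1 mutants without wild-type array 1. In ogt-1 mutants F23F12.12 lost it without wild-type array 3, ogt-1 array 1 or 3, or oga-1 array 2.

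By probe set, 42 were called in both mutants, 27 in the same direction and 15 in opposite directions. Independent lists would give 3.48 higher in both, 1.37 lower in both and 5.15 opposite, but both comparisons use the same 3 wild-type arrays, which links them. Without wild-type array 1, wild-type array 2 or oga-1 array 1 the number called in the same direction was 7, 11 and 13, and without ogt-1 array 1 it was 47. Across all probe sets the log2 changes of the mutants correlated at r = 0.0838, where shared controls and no effect gave 0.50 (0.478 to 0.518) in 100 simulations. An r falls when the changes of one mutant vary more, and the covariance was 0.00650, against 0.00778 on average in simulation. The r was 0.214 without wild-type array 3 and 0.00876 without ogt-1 array 3.

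**Figure D3:**
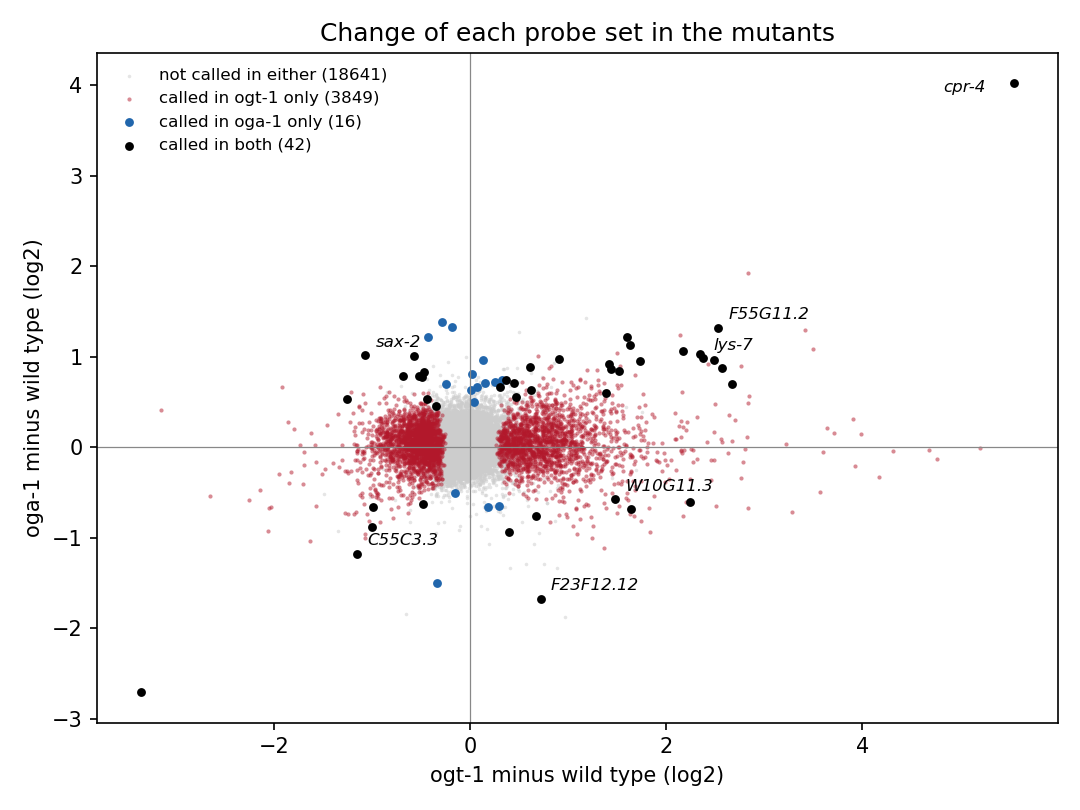
Log2 change of each probe set in ogt-1 mutants (horizontal axis) and oga-1 mutants (vertical axis) against the wild type; colours mark 18641 probe sets called in neither mutant, 3849 in ogt-1 alone, 16 in oga-1 alone and 42 in both. The gene cpr-4 lies far from all others at the upper right, at 5.55 and 4.02, and the point at the lower left is a probe set that matches 2 gene symbols.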

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

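Chosen only after the result was seen were the tests of gene span, of a weaker signal of worm RNA, and of the germline share. So were those of the point within the larval stage, of array spread, of signal level in the oga-1 lists, and of the genes near ogt-1. The splits of the arrays and the other tests of signal level were set beforehand.

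Results were picked out here when the mutant effects were called in opposite directions and the direct test between the mutants was called too. The log2 difference, ogt-1 minus oga-1 mutants, was 2.39 for F23F12.12, 2.05 for W10G11.3, 1.43 for sshk-1 and 1.34 for nlp-33. It was -2.09 for sax-2, -1.78 for haf-6, -1.47 for cec-4, -1.30 for cyp-35A5, -1.30 for F27C1.2 and -0.97 for rbm-25. By list, the median difference was -0.68 for the proteasome, -0.62 for oocyte genes, -0.43 for the respiratory chain and -0.30 for ribosomal proteins, and 0.50 for lysozymes, 0.31 for insulin-like peptides and 0.21 for neuropeptides. No list call held with an estimated correlation, and the respiratory chain and ribosomal lists lost the oga-1 call after quantile normalization.

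Control probe sets, outside the tested values, were picked out where the mutant and wild-type arrays did not overlap. The hybridisation controls were 0.277 higher in ogt-1 mutants. The 3' minus 5' signal of actin differed by -0.729 in ogt-1 and -0.570 in oga-1 mutants, that of Gapdh by -0.379 and that of ubiquitin by -0.0805 in ogt-1 mutants. Each had an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow, so none passes a threshold of 0.05.

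The pattern of lists of small genes called higher in ogt-1 mutants covers neuropeptides, insulin-like peptides, histones, lysozymes, C-type lectins and sperm genes. These are 6 of the 11 lists called higher. Their median gene spans ran from 411 bases for histones to 1794 for C-type lectins, which are thus not much shorter than all genes, at 2185. A bias by gene span and a shift that depends on signal level were each set against 10000 matched random lists. Of the 6 medians, 6 lay above the central 95% of lists matched on span and 6 above that of lists matched on level. Ribosomal proteins, also small genes, had a median of -0.23. This argues against span or level as the whole cause, but the 6 lists were chosen as called higher. The random lists leave out correlation between genes, so the percentiles do not measure chance. Transcript length was not tested. A weaker signal of worm RNA in the ogt-1 samples, where the hybridisation controls were 0.277 higher, would act on genes through their level. Among the same level-matched lists, the lowest of the 6 medians lay at percentile 99.99. Since the 6 lists were chosen as called higher, that percentile alone does not settle the question. A test set beforehand was dropped after its result was seen: 2 of the 6 medians exceeded the control difference, but subtracting it moves every gene alike and so decides nothing. The median change ran from -0.0179 to 0.00021 in the 6 dimmest of 10 groups by level and from -0.161 to -0.0587 in the 4 brightest, so dim genes lay higher relative to bright ones, which goes with a weaker signal. The level-matched lists carry that trend, and the central 95% of their medians reached from negative to positive values for each of the 6 lists. It ran from -0.0660 to 0.0231 for neuropeptides and from -0.0983 to 0.0765 for sperm genes. Level alone thus gave no clear rise for such genes, which argues against a weaker signal beyond a part within these limits. A difference in RNA amplification that acts on genes other than through level or gene span stays open, since the 3' minus 5' signals differed too, and may contribute. The loss of the transferase, which the design gives as the biological explanation, stays beside it, untested.

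The sperm list was called higher and the oocyte list lower in ogt-1 mutants. A smaller germline share of the RNA alone would lower both lists, but the sperm median was at least 0.204 and the oocyte median between -0.26 and -0.42 whichever ogt-1 or wild-type array was left out. Arrays of the same strain varied widely too. The sperm minus oocyte mean, relative to the wild-type average, ran from -0.324 to 0.236 in the wild type. It ran from 0.455 to 0.805 in ogt-1 mutants, which left a gap of 0.219 between the strains. Random lists matched on level had medians, in their central 95%, from -0.266 to 0.228 for the oocyte list and from -0.0983 to 0.0765 for the sperm list. The observed medians, -0.34 and 0.27, lay outside, at percentiles 0.33 and 100, which argues against signal level as the whole cause. Both lists were picked as called, and the random lists leave out correlation between genes, so these percentiles do not measure chance. A different point within the stage would move genes that cycle with each molt: 219 molting and collagen genes had a median absolute change of 0.0964, at percentile 0 of matched lists, whose central 95% ran from 0.125 to 0.178. The vitellogenins, whose expression starts late, were lower (median -0.35), which goes with an earlier point. Their median lay inside the central 95% of level-matched lists (percentile 5.2) and below that of span-matched lists (percentile 1.35). How far the germline had developed relative to the vulva was not tested and, beside loss of the transferase, may contribute.

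Lists in oga-1 mutants shifted with few genes called, and the median change of all probe sets ran from -0.07 among dim to 0.10 among bright ones. Against a shift with signal level as the whole cause, 8 of the 12 lists kept the call after quantile normalization and lay outside the central 95% of level-matched random lists. These lists were picked as called, so the count does not measure chance. With that normalization the median went from 0.22 to 0.13 for oocyte genes, 0.21 to 0.12 for the proteasome, 0.18 to 0.11 for germline genes and -0.12 to -0.07 for chemoreceptors. Insulin-like peptides went from -0.21 to -0.20 and lysozymes from -0.17 to -0.20. Part of several shifts thus went with the scaling. The spread of the arrays is only partly separable from strain, since 2 of the 3 widest arrays are oga-1 arrays: with it as a covariate 5 of the 12 lists kept the call, and without the 3 widest arrays 4 (in all 6 and 5 lists were called). The spread therefore may account for some of these calls, and loss of the O-GlcNAcase stays beside it, untested.

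Other splits of the 6 arrays of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. In ogt-1 mutants the real split gave 3891 probe sets and the highest other 0, so 1 split gave as many. It gave 21 lists, again 1 split, where the other splits, which mix the strains, gave 6 to 19. In oga-1 mutants the real split gave 58 against 7, so 1 split gave as many, and 12 lists against 15, with 4 splits giving as many. Between the mutants it gave 5381 against 0, so 1 split, and 22 lists against 22, so 2 splits. Splits that called no probe set still called lists at the preset correlation. The number of lists called therefore says little about the strains. For probe sets called in both mutants in the same direction, 3 of 100 groupings of the 9 arrays gave 27 or more. The other two kept the strains together, with the 3 ogt-1 arrays (2930 shared calls, the highest) or the 3 oga-1 arrays (33) as the control, which points to a structure of the samples, that of the strains.

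Among the 100 measured genes nearest ogt-1 on chromosome III, 33 were called in ogt-1 mutants, against a median of 22 over all windows of that size. That is percentile 96.8, and overlapping windows leave open whether background variants linked to the deletion may add to the calls there.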

How the results depend on the processing

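The spread covariate and leaving out the 3 widest arrays were chosen after the data were seen; the other alternatives were planned. Of 138 values of genes named in ogt-1 mutants, 109 neither turned direction nor lost a call in any setting run for single genes. The same held for 18 of 50 in oga-1 mutants and 10 of 10 between the mutants. A call gained in a setting did not count against a value. Single genes were not run with the limits on mean level, an adjusted p under 0.1 or a 1.5-fold minimum. The ogt-1 fall kept its direction and call in each setting run, and oga-1 in oga-1 mutants was never called. Dim signals near background, such as those of oga-1, limit what the arrays show. The cause of each change below was not tested, except that leaving out arrays or probe sets, or a stricter or looser threshold, changes counts by construction.

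Probe sets called in oga-1 mutants, and those called in both mutants in the same direction, numbered 91 and 42 after quantile normalization, 94 and 44 with an intensity trend and robust variance, 848 and 209 with array weights, 198 and 79 at an adjusted p under 0.1, 13 and 10 with the spread covariate, and 3 and 2 without the 3 widest arrays. Without 1 array they ranged from 9 to 89 and from 7 to 47. Between the mutants 3309 were called in the top quartile by level, 2664 with at least 1.5-fold and 2544 without the 3 widest arrays, and in ogt-1 mutants 2052 with at least 1.5-fold. The correlation of log2 changes ranged from 0.00876 to 0.214 without 1 array.

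With an estimated correlation 0, 0 and 0 lists were called, in ogt-1 mutants, in oga-1 mutants and between them, and with fry 22, 0 and 24. In oga-1 mutants 6 were called with the spread covariate and 5 without the 3 widest arrays, among them 5 and 4 of the 12; there the direction of the camera test turned for the stress response list (medians 0.0768 and 0.0403) and, without the widest arrays, for the respiratory chain (0.00443). At an unadjusted p under 0.05, 3312 probe sets passed in oga-1 mutants. In ogt-1 mutants the call of collagens was also lost with array weights, the spread covariate, averaged probe sets and without the 3 widest arrays, and that of UDP-glucuronosyltransferases with array weights and without those arrays. In oga-1 mutants the lysozyme call was lost with array weights, and those of the stress response, respiratory chain and ribosomal lists among probe sets above the median level. Between the mutants the collagen call was lost after quantile normalization and median centring.

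Another probe set of the gene gave the other sign in ogt-1 mutants for daf-1 (0.041), hsp-60 (0.15), ric-3 (-0.087), vit-4 (0.39) and oga-1 (-0.055 and -0.152), and in oga-1 mutants for oma-2 (-0.022), rps-18 (-0.18), str-16 (0.046), svop-1 (0.053) and ogt-1 (-0.19). With the same sign, but not called, it was in ogt-1 mutants -0.095 for clec-57, 0.13 for flp-15, -0.50 for glh-1, -0.40 for pdi-1, -0.29 for rps-9, -0.23 for svop-1, -0.019 and -0.051 for unc-52 and -0.35 for vit-4. The log2 change of oga-1 in ogt-1 mutants, 0.06, ranged from -0.0226 to 0.124 without 1 array, and that of ogt-1 in oga-1 mutants, 0.04, from -0.035 to 0.0791, and was -0.062 after quantile normalization and -0.0087 with array weights. Pseudocounts were not run, since the table is already in log2.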

Other observations

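All tests in this part were chosen only after the values were seen. Gene families outside the fixed lists, 168 families of at least 8 measured genes that share a symbol stem, were tested with limma's camera in each comparison. In ogt-1 mutants the phat genes, of the pharyngeal gland, rose in 6 of 8, with a median log2 change of 1.32 (camera adjusted p = 6.9e-05, and adjusted p = 0.72 with an estimated correlation), phat-4 by 2.42 and phat-8 by 2.19. Transthyretin-related ttr genes rose in 18 of 39 and fell in 6, with a median of 0.31 (camera adjusted p = 6.9e-05, and adjusted p = 0.77 with an estimated correlation), and ttr-26, ttr-27 and ttr-21 changed by 2.77, 2.51 and 2.46. Claudin-like clc genes rose in 9 of 23, with clc-11 at 2.35 and clc-23 at 2.15 (camera adjusted p = 0.0051, and adjusted p = 0.72 with an estimated correlation).

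Lower in ogt-1 mutants were the RNA polymerase II subunits rpb, 5 of 10, with a median of -0.38 and rpb-6 at -0.89 (camera adjusted p = 6.3e-04), the splicing factors prp, 7 of 12 (median -0.41, 0.0054), and the replication helicase mcm, 4 of 8 (median -0.42, 0.0069). With an estimated correlation the adjusted p was 0.77 for each of these 3. Mitochondrial ribosomal mrpl genes had a median of -0.15 in ogt-1 mutants, with 7 of 34 lower, and 0.16 in oga-1 mutants, with 0 of 34 called. The median difference between the mutants was -0.37 (camera adjusted p = 1.1e-05). None of these families was called with an estimated correlation, where the adjusted p was at least 0.716 in ogt-1 mutants, 0.726 in oga-1 mutants and 0.462 between them. The medians given kept their sign after quantile normalization and after median centring, with the mrpl median in oga-1 mutants at 0.13 and 0.21. No comparison with lists matched on signal level is given for these families. Over all probe sets in group 9 of 10 by rising level, the median change was -0.161 in ogt-1 and 0.0961 in oga-1 mutants, so level may account for part. Beside these families, the hybridisation controls were 0.277 higher in ogt-1 mutants. There the 3' minus 5' signal differed by -0.729 for actin and -0.379 for Gapdh.

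The largest fall of any probe set in both mutants belonged to one that matches 2 gene symbols and so stays unnamed, singled out after its values were seen. It read 7.79 ± 0.15 (SD, n = 3) in the wild type, 4.43 ± 0.05 (SD, n = 3) in ogt-1 and 5.09 ± 0.09 (SD, n = 3) in oga-1 mutants, log2 changes of -3.36 and -2.71 (limma adjusted p = 4.1e-09 and 5.1e-08).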
